A study of Mus musculus with 46 samples.

How the data were processed

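RNA was measured by SMART-seq2 with Tn5 library preparation in single E3.5 ICMs, single E5.5 epiblasts and single E4.5 cells, per the labels. Rbbp5 was disrupted in zygotes by injected Cas9 mRNA with guide RNAs or by injected Cre mRNA in floxed embryos, and which of these made each library is not given in the sources used here. The series has 46 samples, of which 33 are RNA libraries and 4 are single-cell methylomes (Brif-seq, a bisulfite protocol for single cells). The 7 H3K4me3 and 2 ATAC libraries were not analysed here.

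The deposited expression values are FPKM, fragments scaled by transcript length and by mapped fragments, in a table of 7186 lines. The submitters' processing notes name Trim Galore 0.6.4, STAR 2.7.3, Bowtie2 2.3.5, MACS2 2.2.6, HOMER 4.10.4, Bismark and the mm10 build without tying each to a data type. The names of 2 genes stood more than once, so 4 lines were left out and 7182 genes used. Those lines were identical over the 20 embryo columns and differed over the 13 single-cell columns, so the single-cell columns may have been made separately, and levels were not tested across the sets. Depth is not given by FPKM. Of low values, 4.3% lay within 0.02 of a whole multiple of the lowest value of the gene, where 4% were due if spread evenly. That check cannot show depth, since it compared values across libraries that are each scaled by their own mapped fragments. Steps within a library were not looked for. Gene positions came from the RefSeq annotation of GRCm38 (mm10), in which 6834 genes matched a single symbol. The methylation tables give, as deposited, counts of reads and of methylated reads and the percent methylated per CpG position. Each listed position had 5 to 299 reads.

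Embryo libraries were compared on log2(FPKM + 1), among genes with a mean FPKM of at least 1 over the libraries compared, with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), a linear model that shares variance between genes. P values were adjusted by Benjamini-Hochberg, and genes under 0.05 were called. The pseudocount of 1 understates log2 changes of genes at low FPKM. The comparisons were KO against WT in E3.5 ICM, KO against WT in E5.5 epiblast, the difference of these effects, and E5.5 against E3.5 in WT. The number of genes at 1 FPKM or more was compared by an exact permutation test over all arrangements of the libraries. Of 25 gene lists, 17 had at least 5 tested genes in the ICM and 17 at E5.5, and they were tested with limma's camera at a preset correlation of 0.01. The lists of oocyte transcripts, genes of the first embryonic divisions, ribosomal proteins and mitochondrially encoded genes had no member among the genes used. Comparisons, lists and the rule for named genes were set before the data were examined.

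The named genes of a comparison were the 12 with the largest log2 change each way among called genes with a mean of at least 10 FPKM in the higher group, without predicted or clone names, pseudogenes, small RNA genes, ribosomal protein genes, Y-linked genes and Xist. Up to 4 members of each list with the smallest p were added, and for the difference of effects 5 genes each way by adjusted p. In single cells they were the 8 each way with the largest ratio of means and a mean of at least 20 FPKM in the higher group, at 1 FPKM or more in each of its cells. Some genes that the rule names are not reported here.

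No paired analysis was possible because the labels name no embryo for the E4.5 cells or the methylomes and no test was made on them. Each list's median of log2((KO mean + 1)/(WT mean + 1)) was placed among 10000 random lists matched in 20 bins of expression. Methylation was averaged over the positions that the 4 tables share, and exact Clopper-Pearson intervals at a 95% level were computed on pooled reads with scipy 1.17.1.

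The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, quantile normalization, median ratio scaling, non-robust empirical Bayes, array weights, a sex covariate from the summed FPKM of Ddx3y, Eif2s3y and Uty (Kdm5d was not used here), replicate number as a block, the 4 embryo groups in 1 fit, a 2-fold minimum, an estimated camera correlation and leaving out each library. Added after the data were seen were a fit without the 3 KO ICM libraries with the fewest genes, fits without every other choice of 3 KO ICM libraries, the number of detected genes as a covariate, and methylation over positions with at least 10 or 20 reads, over each cell's positions and over pooled reads, and a sex covariate at E5.5 and for the difference of effects, where 1 E5.5 library is female.

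The code was tested on simulated data with 50 genes shifted by each of 4 log2 changes. For changes of 1 and -1 the fits recovered 16% and 20% in the ICM, 54% and 32% at E5.5, 2% and 6% for the difference of effects and 34% and 60% for development. For changes of 2 and -2 they recovered 82% and 86%, 90% and 92%, 46% and 50%, and 90% and 84%. False calls were 4.17%, 3.89%, 6.67% and 5.79% of calls. The simulated genes varied independently of each other, so shifts shared by the genes of a library were not simulated and these rates leave them out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.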

Results

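RNA was measured in 33 libraries of mouse embryos that were wild-type (WT) or had a knockout (KO) of Rbbp5, a shared subunit of the enzyme complexes that methylate histone H3 at lysine 4 (H3K4). The inner cell mass (ICM) of single blastocysts at embryonic day (E) 3.5 gave 7 WT and 7 KO libraries, and the epiblast of single embryos at E5.5 gave 3 WT and 3 KO libraries. Single cells of E4.5 blastocysts gave 7 WT and 3 KO epiblast libraries and 1 WT and 2 KO primitive endoderm libraries. CpG methylation was measured in 2 WT and 2 KO single E4.5 epiblast cells. The values are FPKM of 7182 genes, and the sequencing depth behind them is unknown. Rbbp5 itself was not analysed here, so the genotype labels were not checked against the targeted gene.

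WT ICM libraries had 5391 ± 219.8 genes at 1 FPKM or more (SD, n = 7) and KO ICM libraries 4388 ± 659.9 (SD, n = 7), a difference of -1004 genes that exceeded the spread between embryos (exact permutation test, two-sided, p = 0.00117). KO ICM libraries 1, 4 and 6 had the fewest, 3628, 3642 and 3883 genes. Summed FPKM ran from 274851 to 304900 in WT ICM and from 303667 to 334642 in KO ICM. The 10 highest genes held 9.9% to 12.6% of the sum in WT ICM and 10.7% to 17.9% in KO ICM. At E5.5 the WT epiblast had 5776 ± 34.3 genes (SD, n = 3) and the KO epiblast 5650 ± 223.7 (SD, n = 3), with an exact permutation p of 0.4 where 0.1 is the smallest possible. Summed FPKM at E5.5 lay between 285126 and 316342. The E4.5 epiblast cells had 3878 to 4682 genes in WT and 3026, 3628 and 3056 in KO, with sums from 212520 to 278609. The primitive endoderm cells had 3414 genes in WT and 3093 and 3279 in KO.

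**Figure D1:**
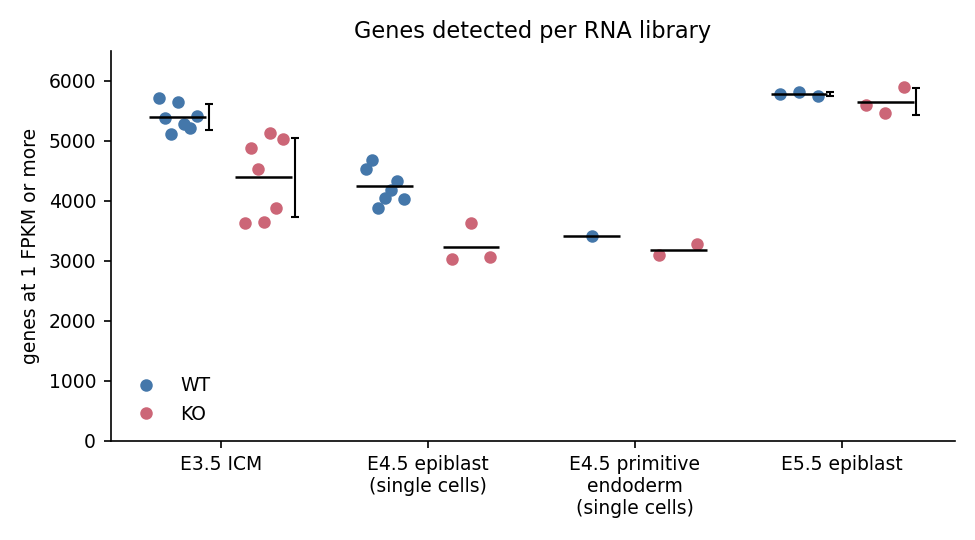
Number of genes at 1 FPKM or more (y axis) in each RNA library by stage and genotype (x axis); points are libraries, horizontal lines are group means, and bars are 1 SD for the E3.5 ICM and the E5.5 epiblast. The KO ICM libraries spread from 3628 to 5136 genes, and the WT ICM libraries from 5110 to 5718.

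The E3.5 comparison asked which genes depend on Rbbp5 in the ICM. Most of the nuclear-encoded respiratory chain list, the subunits of the mitochondrial complexes that make ATP by oxidation, rose in KO ICM, with 39 of 53 members higher and 5 lower. Many more genes fell than rose, among them Phgdh, which starts serine synthesis, and Isyna1, the enzyme of inositol synthesis, whose calls both ended without KO 1, 4 and 6. Ash2l and Wdr5, partners of Rbbp5 in the H3K4 methyltransferase core, also fell. The falls accompanied the smaller number of genes detected in KO ICM. Of 5443 genes tested, 1540 changed, 187 higher and 1353 lower, and 1305 did so by at least 2-fold (67 higher, 1238 lower).

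The median log2 change of all tested genes was -0.65, and it was -0.04 after quantile normalization between libraries and -0.26 after scaling to the median ratio. Changes are therefore given as measured and, where stated, relative to that median. Quantile normalization left 671 genes, 318 higher and 353 lower, of which 479 were among the 1540, and median ratio scaling left 882, 414 higher and 468 lower, of which 655 were.

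Cox7b, a small subunit of cytochrome c oxidase (X: 106015700-106022450, GRCm38), rose from 180.1 ± 67.0 to 495.7 ± 136 FPKM (SD, n = 7 each), a log2 change of 1.49 (SE 0.23, adjusted p = 0.00184). Ndufb2, a subunit of complex I (6: 39592565-39599843), rose by 1.49 from 243.5 ± 70.3 to 721.9 ± 318.2 FPKM (adjusted p = 0.00251). Snhg12, a host transcript of small nucleolar RNAs, rose by 1.59, and Vma21, an assembly factor of the vacuolar proton pump, by 1.38. Cox6b2, the testis form of a cytochrome c oxidase subunit, rose by 1.70, Grcc10 by 1.44, and Wfdc15a by 1.47. Ifitm2 and Ifitm3, interferon-induced membrane proteins, rose by 1.47 and 1.49. Each of these 9 genes was above the WT mean in 7 of 7 KO libraries. Without KO 1, 4 and 6 the calls of Cox6b2 (log2 change 1.40, adjusted p = 0.107), Grcc10 (1.13, 0.0588), Ifitm2 (1.34, 0.0880), Ifitm3 (1.58, 0.0506) and Wfdc15a (0.80, 0.251) ended. With 3 fewer libraries the change of Ifitm3 was as large as before and that of Wfdc15a much smaller. With array weights Wfdc15a had 1.26 (0.0571). Hba-a1, an adult alpha-globin, had a log2 change of 1.75 (adjusted p = 0.0395; 6 of 7 KO libraries). Lxn, a carboxypeptidase inhibitor, had 1.67 (0.0288), and Sct, the hormone secretin, 1.48 (0.0276). Leaving out single libraries ended those calls, with log2 changes of 1.36 to 1.85 for Hba-a1, 1.52 to 1.58 for Lxn and 1.19 to 1.38 for Sct. The adjusted p of Hba-a1 was 0.0776 without KO 1, 0.0620 without KO 2 and 0.0838 without KO 4, and 0.0535, 0.0639, 0.0679, 0.0542, 0.0569 and 0.0808 without WT 1, 2, 3, 4, 6 and 7. That of Lxn was 0.0524, 0.0602 and 0.0559 without KO 1, 4 and 6, and that of Sct 0.0548, 0.0557, 0.0589 and 0.0555 without KO 1, KO 3, WT 1 and WT 6.

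The largest falls, each below the WT mean in 7 of 7 KO libraries, began with Fam151a (4: 106733915-106748292). Its WT libraries had 12.8 to 48.9 FPKM and its KO libraries 4.4e-05, 13.4, 4.66, 0, 7.68, 0.232 and 8.93, a log2 change of -3.38 (SE 0.60, adjusted p = 0.00232). Phgdh (3: 98313171-98339969) fell by 3.09 from 141.9 ± 123.2 to 16.0 ± 14.6 FPKM (SD, n = 7 each, adjusted p = 0.00514). Isyna1 (8: 70594481-70597290) fell by 3.08 from 1291 ± 623.2 to 244 ± 267 FPKM (adjusted p = 0.00367). Cldn4, a tight junction protein of the trophectoderm, fell by 2.97 from an uneven WT level (2.585 to 88.15 FPKM). Ctsz, a lysosomal protease, fell by 2.93. Vti1b, which serves membrane fusion, fell by 2.85, Slc2a8, a glucose transporter, by 2.79, and Usf1, a transcription factor, by 2.79. The others were Klhl22 (-2.94), Dus1l (-2.92), Rtkn (-2.79) and Rcl1 (-2.78). Without KO 1, 4 and 6 Phgdh had -2.09 (adjusted p = 0.0662), Isyna1 -1.80 (0.0518) and Dus1l -1.93 (0.0525), no longer called.

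The respiratory chain list had a median log2 change of 0.93, or 1.59 relative to all genes and 0.98 relative to lists matched on gene span and WT mean, and 40 members were higher and 6 lower adjusted over the list alone. Cox8a rose from 2137 ± 312.6 to 4560 ± 1129 FPKM, Cox5b from 653.6 ± 115.2 to 1381 ± 285.7, and Cox6c from 1041 ± 186.2 to 2723 ± 1074 (SD, n = 7 each). The 5 that fell, Uqcrc1 (-2.12), Uqcrc2 (-0.92), Ndufv1 (-1.03), Ndufs1 (-0.94) and Ndufa9 (-0.61), were named after their values were seen. It was the only 1 of 17 lists that camera called (adjusted p = 3.38e-46), and the call held with adjusted p = 0.00649 with an estimated correlation.

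**Figure D2:**
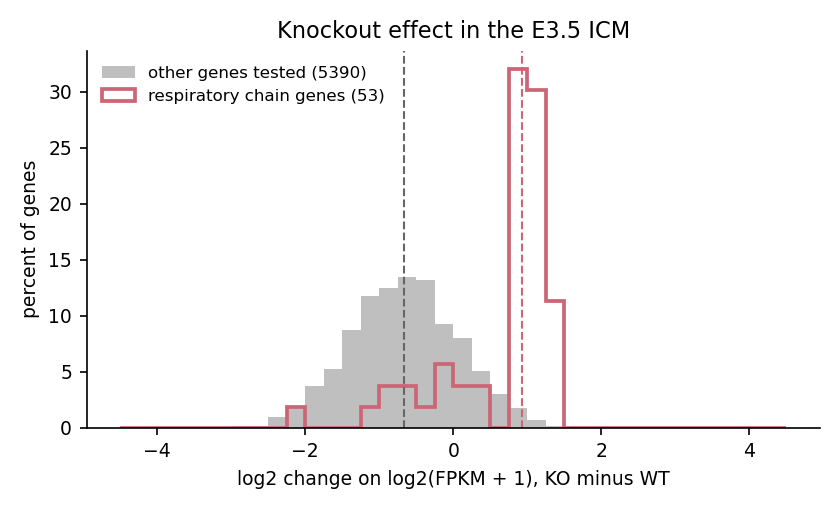
Percent of genes (y axis) by log2 change of KO against WT ICM (x axis, log2 of FPKM + 1) for the 53 respiratory chain genes (outline) and the 5390 other genes tested (filled); dashed lines are medians. The median is 0.93 for the respiratory chain and -0.66 for the other genes.

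None of the other 16 lists passed. Glycolysis had 7 of 9 genes lower (7 adjusted over the list alone), a median of -1.48 or -0.83 relative to all genes, and a camera adjusted p of 0.124. In it Eno1, an enolase, fell by 1.78 (to 31.2 ± 18.1 FPKM, SD, n = 7), and Slc2a1, the main glucose transporter, by 2.26. Of 16 targets of p53, the tumour suppressor, 6 were lower (9 adjusted over the list alone), with a camera adjusted p of 0.0896. They included Sesn2, a stress sensor (-2.16), Plk2, a kinase (-2.13), and Mdm2, the ligase that degrades p53 (-1.48), whose adjusted p rose from 0.00649 to 0.0506 after quantile normalization. DNA replication had 11 of 24 genes lower (13 adjusted over the list alone; camera adjusted p = 0.252), among them Mcm6 of the replicative helicase (-1.89). Mitosis had 9 of 19 lower (1 higher and 11 lower adjusted over the list alone; 0.312), among them Cdc20 (-2.26), Kif20a (-2.72) and Aurka (-2.44), which drive chromosome separation and cell division. Quantile normalization brought glycolysis (adjusted p = 0.00646), mitosis (0.00841), the p53 targets (0.0338) and DNA replication (0.0434) past the threshold, all lower.

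Among the H3K4 methyltransferase complexes 3 of 9 genes were lower (4 adjusted over the list alone; camera adjusted p = 0.756). Ash2l fell by 1.82 (SE 0.33) from 69.2 ± 21.3 to 20.8 ± 12.2 FPKM (SD, n = 7 each, adjusted p = 0.00251) and Wdr5 by 1.64 (adjusted p = 0.00543). Hcfc1, a cofactor of the complexes, had -1.33 (adjusted p = 0.00925), or 0.0978 after quantile normalization. The stress response to amino acid shortage had 4 of 9 lower (4 adjusted over the list alone; 0.501), the trophectoderm markers 4 of 10 (4; 0.704), the germline genes held by DNA methylation 3 of 6 (3; 0.704), and the visceral endoderm markers 2 of 5 (2; 0.704). Tead4, a trophectoderm transcription factor, fell by 2.21. Primitive endoderm markers had 2 of 10 lower (2 adjusted over the list alone; 0.902), naive pluripotency 2 of 11 (0 adjusted over the list alone; 0.902), formative epiblast 1 of 5 (1; 0.902), and imprinted genes 1 of 8 (0 adjusted over the list alone; 0.756).

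The DNA methylation machinery (8 genes), core pluripotency (8) and FGF signalling (6) had 0 calls with limma over all genes and 0 adjusted over the list alone, with a camera adjusted p of 0.756 each. For these lists, the imprinted genes and the primitive endoderm markers, medians lay below 0 (-0.38, -0.42, -0.52, -0.41 and -0.47) while camera pointed up relative to other genes. Nanog, a factor of the naive epiblast, had 186.0 ± 80.9 FPKM in WT and 111.3 ± 75.5 in KO (adjusted p = 0.0716), and Pou5f1, which encodes OCT4, 49.6 ± 24.8 and 29.9 ± 13.3 (SD, n = 7 each, adjusted p = 0.161). Of the markers of blood and maternal tissue, too few for a list test, Hba-a1 rose, to as much as 40.6 FPKM in a KO library, Pecam1 fell by 1.78, and Des had -0.81 (adjusted p = 0.258). Of 4 extraembryonic ectoderm markers and 4 H3K4 demethylases tested singly in the ICM, 0 passed with limma.

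The ICM count depended on which KO libraries were kept. Without KO 1, 4 and 6, those with the fewest detected genes, it was 405 (77 higher, 328 lower; 394 among the 1540), and 36 of the 62 calls among named genes were lost, those of Eno1, Slc2a1, Plk2 and Hcfc1 among them. The 34 other choices of 3 KO libraries left out gave 246 to 2517 genes, with a median of 1192, and 2 of them gave as few as 405. With the number of detected genes as a covariate it was 0 with limma, with 314 at an unadjusted p under 0.05. Leaving out WT 1 gave 946 and WT 4 gave 987. The respiratory chain list passed without KO 1, 4 and 6, with detected genes, and without WT 1 or WT 4, but its median relative to all genes went from 1.59 to 1.05 without KO 1, 4 and 6 (1.25 to 2.07 for the 34 other choices) and to 0.46 with detected genes in the fit.

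The E4.5 single cells asked how the epiblast and the primitive endoderm, the layers that form from the ICM, differ without Rbbp5. The labels name no embryo for these cells, so each group counts as 1 sample, nothing was tested, and the values describe these cells alone. Nanog had 721.4, 724.6 and 222.2 FPKM in KO epiblast cells 1, 2 and 3, against 59.6 to 252.9 in the 7 WT cells. Klf4 and Tbx3, other factors of the naive state, had 106.8, 87.5 and 40.8 FPKM and 144.8, 99.3 and 9.47 FPKM, against 0.0475 to 37.3 and 3.52 to 31.6. Dnmt3l, a cofactor of de novo DNA methylation, had 0.763, 0.357 and 207.9 FPKM against 132 to 427.5. Dnmt3a and Dnmt3b, the de novo DNA methyltransferases, had 0, 0.244 and 28.1 FPKM and 0.0455, 0.101 and 30.1 FPKM, against 1.15 to 154.9 and 10.6 to 81.4. These markers were chosen after their values were seen. OCT4's gene Pou5f1 had 1167, 1211 and 513.8 FPKM, against 588 to 1191.

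**Figure D3:**
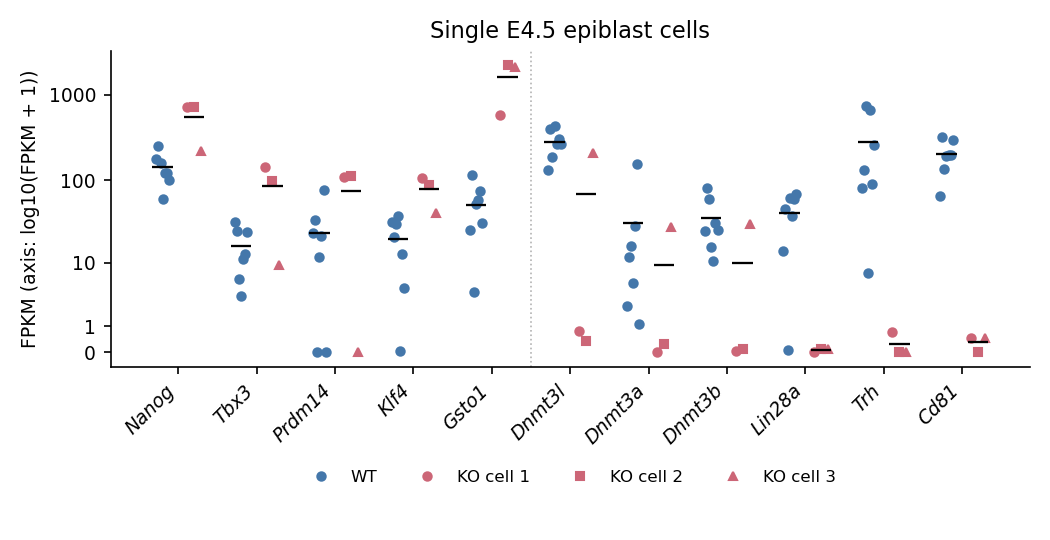
FPKM of single E4.5 epiblast cells on a log axis (y axis) for selected genes (x axis); points are cells, 7 WT and 3 KO (a marker shape for each KO cell), horizontal lines are means over cells, and no error is drawn because the embryos are not named. The axis is log10 of FPKM + 1. KO cells 1 and 2 have Dnmt3l at 0.763 and 0.357 FPKM and KO cell 3 has 207.9.

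By the rule for named genes, Gsto1, a glutathione transferase, had 578.2, 2220 and 2089 FPKM in the KO epiblast cells against 4.04 to 114.7 in WT. Anxa1, a phospholipid-binding protein, was listed at 0 in every WT cell and at 21.2, 12.8 and 72.4 in KO. The others higher in KO were S100a1, Stk36, Abcg1, Taf1c, Atg16l2 and Magt1. Lefty2, an inhibitor of Nodal, was listed at 0 in the 3 KO cells against 14.6 to 298.2 FPKM in WT, as was Uchl1 against 15.9 to 294.4. Trib3, a pseudokinase of the stress response, had 0.188, 0.0949 and 0.0949 FPKM against up to 221.5 in WT. The others lower were Trh, Cd81, Aire, Traf7 and Bcam.

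Of 17 lists in the epiblast cells, 8 had a median outside the central 95% of 10000 random lists matched on expression. Glycolysis had a median log2 ratio of -1.82 and the amino acid stress response -1.99, both at percentile 0.0, with Eno1 at no more than 122.8 FPKM in KO cells against 241.9 to 1639 in WT. DNA replication (-1.11), imprinted genes (-2.42), FGF signalling (-2.22), the respiratory chain (-0.52) and formative epiblast (-1.64) also lay low. Trophectoderm markers lay high at 0.99, but their median was -0.10, 0.28 and 0.06 without KO cells 1, 2 and 3. The other 9 lay inside: mitosis -0.58, DNA methylation machinery -0.73, core pluripotency -0.45, H3K4 demethylases -0.72, germline genes -0.43, primitive endoderm markers -0.65, H3K4 complexes 0.06, naive pluripotency 0.49 and p53 targets 0.51. The p53 median was -0.265 without KO cell 3 and 0.94 without WT cell 7, and that of germline genes 0.15 with medians over cells. Without KO cell 2, 5 lists lay outside. The respiratory chain median was -1.38, -0.84 and -0.09 in KO cells 1, 2 and 3, so KO cell 3 did not share the fall. The difference from KO ICM was not tested. In the same order DNA replication had -3.45, -1.55 and -0.38, and formative epiblast -1.80, -4.71 and -0.24. Of the lists inside, mitosis had -4.23, -1.68 and 0.30. The DNA methylation machinery had -2.95, -2.49 and -0.13, and its median was -2.72 without KO cell 3. Glycolysis, the stress response, imprinted genes and FGF signalling lay below 0 in each KO cell. Medians of single cells were taken against the mean of the WT cells and were not placed among random lists. No WT cell was scored in that way, so how often a single WT cell would lie below 0 is unknown.

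In the primitive endoderm cells Cdkn1a, the cell cycle inhibitor induced by p53, had 1026 and 972.2 FPKM in KO against 1.82 in the single WT cell. Gadd45g, a growth arrest gene, had 448.8 and 243.2 FPKM against 0.273. Cryab, a small heat shock protein, had 103.7 and 398.3 FPKM against 0.322, and Gas6, a receptor ligand, 210.3 and 217.9 against 0.0578. Usf1 was listed at 0 in WT, with 102.9 and 201.3 FPKM in KO, and Pcca, Dctn6 and Slc25a20 were also higher. Amn, needed for nutrient uptake by endoderm, had 0 and 0.251 FPKM against 745.8, and Trib3 0.312 and 0.198 against 297.9. Utf1, a pluripotency gene, had 1.04 and 1.66 FPKM against 322.0, and Dtd1 was listed at 0 in both against 145.5. Nefl, Akt1s1, Fam173a and Gltscr2 were also lower.

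Of 15 lists in the primitive endoderm cells, 3 lay outside the central 95% of random lists: p53 targets with a median of 4.13 (percentile 100), glycolysis with -1.84 (0.01) and primitive endoderm markers with -1.11 (0.19). The respiratory chain, at 0.43, lay inside, as did core pluripotency (-0.74), imprinted genes (-2.92), DNA methylation machinery (-1.10), the amino acid stress response (-0.31), formative epiblast (-1.41), mitosis (0.04), trophectoderm markers (-0.67), DNA replication (-0.03), H3K4 complexes (-0.48), naive pluripotency (1.52) and H3K4 demethylases (2.68). The values of 1.52 and 2.68 come from the mean of the KO cells and appear in neither cell. In KO cells 1 and 2 the naive median was -0.84 and -0.06 and the demethylase median 0.10 and 0.0. The naive median was 0.03 without KO cell 1 and -1.73 without KO cell 2. With 1 WT cell all these values compare cells, not genotypes.

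The methylation tables asked whether DNA methylation differs in the KO epiblast. At the 74 CpG positions that every table listed, the mean level was 84.6% and 81.9% in the WT cells and 92.3% and 84.3% in the KO cells, with a median of 54 to 58.5 reads per position. The KO mean lay 5.0 points above WT, while the WT cells differed by 2.73 points and the KO cells by 8.0. As a median over positions the difference was 0.29 points, and over positions with at least 20 reads 0.79. Pooled over reads the levels were 93.5% (95% exact Clopper-Pearson interval 92.8 to 94.2) and 90.6% (89.8 to 91.4) in WT and 96.3% (95.7 to 96.7) and 92.8% (92.0 to 93.4) in KO. The intervals take each read as an independent draw, which reads from the same position of a single cell need not be. They cover counting error only, under that assumption, and can be too narrow, so they do not set the cells apart. Of these positions, 70 fell in 5 regions, and 4 regions had mean levels between 88.5% and 96.5% in each cell. In the region at 4: 118547298-118548313 (mm10; 13 positions, in the noncoding RNA gene Gm40237) KO cells 1 and 2 had 86.4% and 42.7% and WT cells 1 and 2 47.8% and 30.4%, at a median of 10, 18, 13 and 29 reads. No position listed for any cell was fully methylated or fully unmethylated, so the tables hold intermediate positions only. The means above are levels of those positions and not of the cells. The positions are too few and too clustered to stand for the genome.

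The E5.5 comparison asked which genes depend on Rbbp5 in the epiblast after implantation. Genes of the trophoblast, the lineage of the placenta, rose in KO epiblast: 13 of 13 trophectoderm markers and 5 of 6 extraembryonic ectoderm markers were higher. Pluripotency genes fell, with 6 of 8 core genes lower, among them Pou5f1, and 5 of 8 formative genes lower, among them Otx2, which marks the epiblast about to differentiate. The DNA methyltransferases Dnmt3a and Dnmt3b fell, and the growth-related imprinted genes H19 and Igf2 rose. Of 5956 genes tested, 2032 changed, 928 higher and 1104 lower, 615 and 753 of them by at least 2-fold.

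The largest rise was that of Ly6a, a surface protein of stem cells (15: 74994877-74998031). Its WT libraries had 0.164, 0 and 0.306 FPKM and its KO libraries 238.2 ± 41.7 (SD, n = 3), a log2 change of 7.69 (SE 0.23, adjusted p = 2.97e-08). Gata3, a transcription factor of trophoblast (2: 9857078-9887953), rose by 6.58 from 0.427 ± 0.259 to 147.4 ± 82.2 FPKM (SD, n = 3 each, adjusted p = 1.83e-06). H19, an imprinted noncoding RNA (7: 142575530-142578146), rose by 6.76, from 2.46 to 3.99 FPKM in WT libraries to 484.2 ± 282.5 FPKM in KO (SD, n = 3, adjusted p = 1.23e-05). Krt19, a keratin of epithelia, rose by 6.10 from 1.79 ± 0.929 to 190.0 ± 66.1 FPKM (SD, n = 3 each). The connexin gene Gjb5, whose product forms gap junctions, rose by 6.36. The others were Tinagl1 (6.92), Gsta1 (6.51), Ndrg1 (6.37), Ddah1 (5.95), S100a6 (5.92) and Plaur (5.74).

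Id3, a target of BMP signalling (4: 136143822-136145392), fell by 5.78 (SE 0.90) from 248.2 ± 49.5 to 8.16 ± 12.2 FPKM (SD, n = 3 each, adjusted p = 0.00247). Pou5f1 (17: 35506032-35510777) fell by 3.94 (SE 0.49) from 139.9 ± 45.1 to 9.84 ± 8.70 FPKM (SD, n = 3 each, adjusted p = 0.000785). Otx2 (14: 48656781-48667644) fell by 3.51 from 98.9 ± 5.94 to 11.1 ± 11.5 FPKM (SD, n = 3 each, adjusted p = 0.00418). Pim2, a kinase, fell by 4.12, and Foxh1, a partner of Nodal signalling, by 3.70. The others were Gstt2 (-3.91), Cd24a (-3.76), Cyct (-3.70), Pla2g1b (-3.54) and Dtx3 (-3.50). Each of these genes moved its way in 3 of 3 KO libraries.

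**Figure D4:**
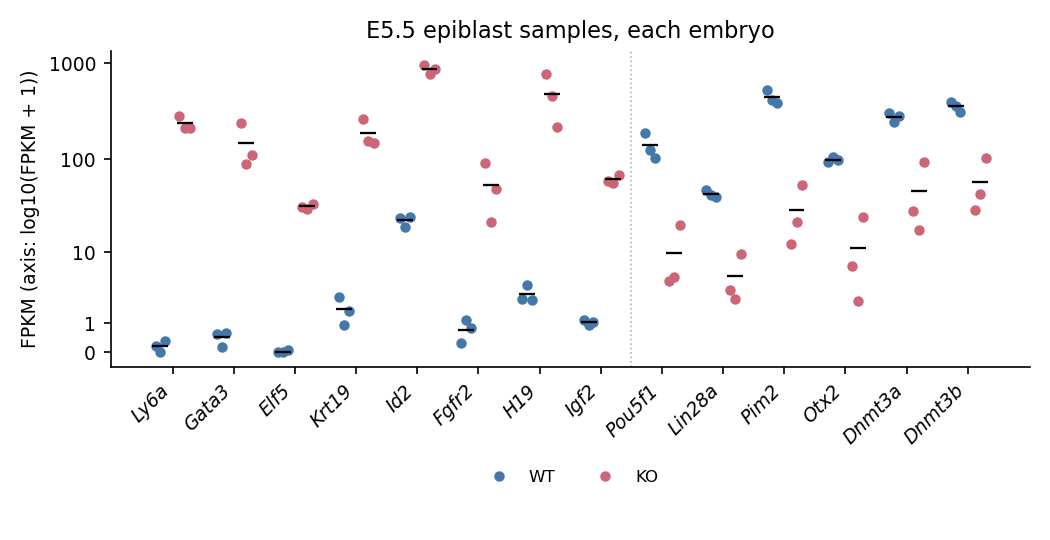
FPKM on a log axis (y axis) of selected genes (x axis) in single E5.5 epiblasts; points are libraries, 3 WT and 3 KO, horizontal lines are means, and the axis is log10 of FPKM + 1. Gata3 has a mean of 0.427 in WT and 147.4 in KO, and Pou5f1 139.9 and 9.84.

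Camera called 7 of the 17 lists tested at E5.5, where other divisions of the same libraries into groups gave a median of 6 and up to 7. The trophectoderm markers (13 higher adjusted over the list alone) had a median log2 change of 4.80 (camera adjusted p = 3.82e-14; adjusted p = 0.410 with an estimated correlation). Id2, an inhibitor of differentiation, rose from 22.5 ± 3.05 to 871.8 ± 88.3 FPKM (SD, n = 3 each), and Elf5, a trophoblast stem cell factor, from 0, 0 and 0.0451 FPKM to 31.7 ± 1.64 (SD, n = 3). Fgfr2, the FGF receptor of that lineage, rose by 4.80. The extraembryonic ectoderm markers (5 higher adjusted over the list alone) had a median of 3.69 (5.07e-05; adjusted p = 0.410 with an estimated correlation), and Elf5 and Fgfr2 stand in both lists. Endoderm markers showed little of this, though only 6 of 15 visceral endoderm markers were among the genes used. The median of 21 visceral and primitive endoderm markers was 0.149 FPKM in WT and 0.329 in KO, and the highest, Cited1, had 19.2 in KO. Of these 21 markers 6 were tested, with 3 higher and 1 lower. Of blood and maternal markers Pecam1 rose by 1.48, and Des had -0.90 (adjusted p = 0.183). Of the primitive streak and Nodal genes, too few for a list test, Nodal had -1.82 (adjusted p = 0.0640), Lefty1 0.58 (0.575) and Lefty2 -0.49 (0.297).

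Core pluripotency (6 lower adjusted over the list alone) had a median of -1.82 (camera adjusted p = 0.000302; adjusted p = 0.567 with an estimated correlation). In it Lin28a, an RNA-binding protein of stem cells, fell from 43.2 ± 3.66 to 5.18 ± 3.74 FPKM (SD, n = 3 each), and Gdf3, a ligand of the Nodal pathway, fell by 2.68. Formative epiblast (6 lower adjusted over the list alone) had a median of -2.60 (0.00725; adjusted p = 0.567 with an estimated correlation). The DNA methylation machinery had 1 of 8 genes higher and 6 lower, the same adjusted over the list alone (0.0430; adjusted p = 0.567 with an estimated correlation). Dnmt3b fell from 357.1 ± 40.2 to 58.1 ± 39.0 FPKM and Dnmt3a from 277.3 ± 31.2 to 46.9 ± 41.5 (SD, n = 3 each), while Tet2, a demethylating enzyme, rose by 2.07. DNA replication had 9 of 25 genes lower, the same adjusted over the list alone (0.00725; adjusted p = 0.635 with an estimated correlation), among them Mcm2 from 202.1 ± 15.7 to 76.0 ± 10.4 FPKM. The respiratory chain had 16 of 53 higher and 1 lower, the same adjusted over the list alone (0.000517; adjusted p = 0.782 with an estimated correlation), among them Ndufa12 from 115.9 ± 10.9 to 258.1 ± 7.30 FPKM (SD, n = 3 each). With an estimated correlation 0 lists passed in limma's camera, and 2 had an unadjusted p under 0.05, the trophectoderm (0.0483) and extraembryonic ectoderm (0.0317) markers.

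The other 10 lists did not pass. Imprinted genes had 6 of 14 higher and 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.173): Igf2, a growth factor, rose from 1.05 ± 0.113 to 61.6 ± 6.08 FPKM (SD, n = 3 each) and Slc38a4, an amino acid transporter, by 3.74, while Nnat fell by 2.89. Glycolysis had 5 of 12 higher and 2 lower (5 and 2 adjusted over the list alone; 0.514), with Slc2a1 up by 1.46, Hk2, a hexokinase, by 1.37 and Ldha, a lactate dehydrogenase, down (-0.71). The amino acid stress response had 3 of 9 higher and 1 lower (3 and 1 adjusted over the list alone; 0.662), and Asns, asparagine synthetase, rose by 2.73. The H3K4 complexes had 1 of 9 higher and 4 lower (1 and 4 adjusted over the list alone; 0.362), with Hcfc1 at -1.42 and Cxxc1, a subunit that binds CpG islands, at -1.40. FGF signalling had 1 of 6 higher and 3 lower (2 and 3 adjusted over the list alone; 0.830), and Fgf4, the ligand made by the epiblast, fell by 2.08.

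Germline genes had 1 of 7 higher, Tex19.1 with 2.66, and 4 lower (1 and 5 adjusted over the list alone; 0.239). Naive pluripotency had 2 of 7 higher and 2 lower (2 and 2 adjusted over the list alone; 0.687), with Klf5 up by 3.71. The p53 targets had 3 of 16 higher and 2 lower (2 and 2 adjusted over the list alone; 0.514), and Bax, which promotes cell death, fell by 1.67. Mitosis had 2 of 19 higher and 3 lower (2 and 3 adjusted over the list alone; 0.830), and the H3K4 demethylases 0 of 5 higher and 1 lower (1 adjusted over the list alone; 0.749), Kdm5b with -1.21. Median and camera differed in sign for the stress response (-0.09, up) and the demethylases (0.01, down), and for FGF signalling the median (-0.37) and mean (0.08) did.

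The 3 WT epiblasts came from male embryos by their Y-linked genes and 2 of the 3 KO did, so a sex term, added after the data were seen, rests on KO 1 alone. With it 1677 genes changed (778 higher, 899 lower; 1584 among the 2032), and the DNA methylation machinery was not called (camera adjusted p = 0.0569). Leaving out WT 1 gave 1205 changed genes and WT 2 gave 1293; with all 4 embryo groups in 1 fit it was 561 (303 higher, 258 lower; 554 among the 2032), and 29 of 77 calls among named genes were lost, those of Mcm2, Slc2a1, Hk2, Ldha, Asns, Bax, Fgf4 and Cxxc1 among them. That fit leaves the log2 changes as they were (Mcm2 -1.41, Asns 2.73) and alters the error and the set of genes tested. It tested 5917 genes against 5956, with 1928 of the 2032 among them.

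A further test asked for which genes the KO effect differed between the stages. Gsto1, already high in the ICM (1361 ± 435 FPKM in WT, 1299 ± 333 in KO, SD, n = 7 each), went from 34.5 ± 7.80 to 1570 ± 430.0 FPKM at E5.5 (SD, n = 3 each), a difference of log2 changes of 5.52. The other genes named by adjusted p had a mean under 1 FPKM in WT and KO ICM, so there is no ICM effect to compare and their values are the change at E5.5. H19, Rhox4a, Rhox4c, Rhox4e and Bcl11a were listed at 0 in all 14 ICM libraries. Rhox4a, a homeobox gene of extraembryonic tissue, went from 0.331 ± 0.291 to 39.3 ± 9.95 FPKM at E5.5 (SD, n = 3 each), a log2 change of 4.91 (SE 0.29, adjusted p = 2.38e-06 in the E5.5 fit). Rhox4c (4.14) and Rhox4e (4.35) are near copies of it that can share reads, which leaves their values uncertain. Slc16a3, a lactate exporter, went from 116.2 ± 14.3 to 15.7 ± 2.38 FPKM at E5.5 (SD, n = 3 each), and Bcl11a, a transcription factor, fell by 2.81, Nnat by 2.89, Calca by 3.42 and Dtx1 by 2.94.

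Of 5917 genes 827 differed, 627 with a higher and 200 with a lower effect at E5.5, and the median difference of all genes was 0.56. Of the 827, 108 had a mean under 1 FPKM in WT and KO ICM, and 719 of 5593 differed among the rest. After quantile normalization that median was 0.00 and the count 752 (410 higher, 342 lower), and after median ratio scaling 0.16 and 607 (340 higher, 267 lower). The count was 1664 with array weights (1284 higher, 380 lower) and 520 with a pseudocount of 0.1 (409 higher, 111 lower). Relative to the median the difference was 4.96 for Gsto1, which the ICM expresses. Leaving out KO epiblast 1 gave 458 genes, WT epiblast 1 gave 489 and WT epiblast 2 gave 496. Of 5143 genes tested at both stages, 42 rose at both against 29.8 expected from independent lists (Fisher's exact test over genes, Benjamini-Hochberg adjusted p = 0.0245), and 248 fell at both against 212 (0.00820). Genes are not independent replicates, and the correlation of changes across genes was small (Pearson r 0.03, Spearman rho 0.06).

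Development in WT embryos served as a reference, with 11 of 18 lists called by camera and 2 with an estimated correlation. The respiratory chain had the smallest p, with 29 of 53 members lower and 2 higher from E3.5 ICM to E5.5 epiblast (median -0.49, camera adjusted p = 1.40e-08; adjusted p = 0.201 with an estimated correlation), opposite to its rise in KO. The lists called both ways were the formative and naive genes: 7 of 8 formative genes rose and 0 fell (camera adjusted p = 3.61e-05; adjusted p = 0.0140 with an estimated correlation), and 9 of 11 naive genes fell and 1 rose (3.61e-05; adjusted p = 0.0140 with an estimated correlation). Of 6022 genes 3388 changed, 2247 higher and 1141 lower, or 1659 and 1488 after quantile normalization, which moved the median change from 0.43 to 0.09. Dnmt3b rose by 6.11 (SE 0.34, adjusted p = 1.28e-08) from 4.52 ± 2.03 (SD, n = 7) to 357.1 ± 40.2 FPKM (SD, n = 3), and Nanog fell by 3.53 from 186.0 ± 80.9 (SD, n = 7) to 14.4 ± 3.49 FPKM (SD, n = 3).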

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

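The covariate test of the respiratory chain, its splits, the tests of tissue carry-over at E5.5, and the intervals used for carry-over and dropout were chosen after the results were seen; the others were written beforehand.

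Respiratory chain genes rose in KO ICM while many other genes fell, and KO libraries had fewer detected genes. A bias by gene span and abundance is argued against as the whole cause, since the list's median of 0.93 lay above all 10000 lists matched on span and WT mean (highest 0.49). Those lists had a median of -0.05 against -0.65 for all genes, so the excess over like genes was 0.98 rather than 1.59, while over single genes the log2 change had almost no rank correlation with span (-0.00919) or WT mean (-0.0547). Whether span and abundance add to the rise relative to all genes stays open. Span here is the genomic extent with introns, so a bias by transcript length was not tested. Lower capture of transcripts in KO libraries stays open for the genes that fell: 67.6% had a slope on detected genes among the WT libraries above the median slope, below the upper bound of 70.4% from the 5040 orders of those libraries. It stays open for the respiratory chain too, whose median relative to all genes went from 1.59 to 0.46 with detected genes in the fit, so 29.1% was kept (24.1% to 33% leaving out each library), and genotype and detection cannot be told apart there. No biological explanation was tested.

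Trophoblast genes rose and epiblast genes fell in KO E5.5 epiblast. A minor carry-over of extraembryonic tissue is argued against as the whole cause in KO 1 and 2, since it would leave epiblast genes near WT. There the 16 core and formative epiblast genes stood at a median of 12.5% and 12.6% of the WT level, under the 50% bound. The 95% intervals over genes, from order statistics, were 6.93% to 33.9% and 4.91% to 39.9%. In KO 3 a minor carry-over as the whole cause stays open, since the median of 36.6% has an interval of 21.9% to 91%. The fall of these genes is itself part of the pattern, so whether a minor carry-over supplied the trophoblast RNA stays open in each KO library. Carry-over of visceral endoderm is argued against, as far as the measured markers show it, by a median of 0.329 FPKM. That median is over 21 visceral and primitive endoderm markers and lay under the bound of 10 FPKM. Only 6 of 15 visceral endoderm markers were among the genes used, Cited1 highest with 19.2 FPKM in KO. What the missing markers would show was not tested. KO samples made mostly of extraembryonic ectoderm cannot be told apart from epiblast that took on trophoblast expression, as 16 of 17 markers were higher under either. Neither is favoured by these values, and a change of fate in KO epiblast remains a hypothesis that was not tested.

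In E4.5 KO epiblast cells 1 and 2 Dnmt3l was at 1 FPKM or less and Nanog above the WT range. Of 219 genes at 100 FPKM or more in every WT cell, 3 genes (1.37%, exact 95% interval up to 3.95%) were at 1 FPKM or less in KO cell 1 and 3 (1.37%) in KO cell 2, Dnmt3l among them in both, against 0 in each WT cell held out. Among genes at that WT level, dropout of 10% or more is argued against. A smaller share, that of Dnmt3l included, stays open: the 1.37% lay under the 2% bound set beforehand, but its interval reaches past it. Genes at lower WT levels, Dnmt3a and Dnmt3b among them, were outside this count, so their dropout stays open. A score of ICM genes over E5.5 epiblast genes was 1.45 in KO cell 1 and 1.17 in KO cell 2, against -1.51 to -0.88 in the WT cells, so an earlier, ICM-like stage is a candidate explanation. The score was also above WT in KO cell 3 (0.045), which lacks the pattern, in the KO primitive endoderm cells (2.85 and 1.14 against -0.197) and in the KO E5.5 libraries (-0.556, -1.19 and -1.13 against -2.95 to -2.80), so it is not particular to cells 1 and 2. Whether that is delay from the KO or a different age of unnamed embryos stays open.

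Other splits of the same libraries were fitted. In the ICM 1 of 100 splits, the real one, gave as many as 1540 genes (highest other 951), and chance is excluded. For the list count chance is not excluded, since 78 of 100 splits gave at least the 1 list (highest other 4), but 1 of 100, the real one, gave a respiratory chain median as large as 1.59 (highest other 1.42). At E5.5 the 10 splits are too few for a share under 0.05. The real one gave 2032 genes and the highest other 0, so 1 split was as large. For lists the real one gave 7 and the highest other 7, so 2 splits were as large. The other splits had a median of 6 called lists, so at the preset correlation the count of 7 does not set the real split apart. Chance is excluded for development, where 1 of 100 splits, the real one, gave as many as 3388 genes (highest other 4). For the difference of effects 1 of 100, the real one, gave as many as 827 (highest other 666). Those splits shuffle genotype within both stages, which removes the KO effect at each. They therefore speak to whether there is any KO effect, and cannot exclude chance for a difference between the stages.

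A library lay far from the others of its group for 10 of 139 groups of values, where chance gives 7.0, about 1 in 20. The gap to the nearest library over the range was 0.695 for Cox6b2 and 0.660 for Ifitm2 (both WT ICM 6), 0.596 for Grcc10 (KO ICM 1), 0.713 for Fam151a, 0.672 for Sesn2, 0.685 for Aurka and 0.620 for Hcfc1 (each WT ICM 5), 0.630 for Isyna1 (WT ICM 2), 0.589 for Mt1 (WT ICM 3) and 0.635 for Lin28a (WT E4.5 epiblast cell 3), each above Dixon's critical value for 7 libraries.

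Of 114 named genes, 65 had a KO effect that differed between E5.5 epiblast and E3.5 ICM, against 827 of all 5917 genes tested. Many of them were named for a large change at a stage, and 10 for the smallest adjusted p of this same test, 5 each way, so the share among them is raised by that choice. Of the 65, 12 had a mean under 1 FPKM in WT and KO ICM, so there is no ICM effect to compare and the value is in essence the E5.5 change: Bcl11a, Calca, Dtx1, Elf5, H19, Krt19, Nnat, Rhox4a, Rhox4c, Rhox4e, Rhox6 and Slc16a3. Of all 827, 108 were such genes. Fam151a was not tested at E5.5, so its value is in essence the ICM change of -3.38. A fit with the number of detected genes was not run for the difference of effects. WT ICM libraries were uneven for Gata3 (1.47 to 186.5 FPKM), Krt8 (17.1 to 239.9) and Cldn4 (2.585 to 88.15), less so for Tead4 (6.16 to 14). The ICM part of the first 3 differences rests on that uneven level. The ICM call of Gata3 ended after quantile normalization (limma adjusted p = 0.1125). The difference of log2 changes, E5.5 minus E3.5, was Gata3 9.04, Tinagl1 7.85, Ly6a 7.61, Ndrg1 7.60, Plaur 7.46, H19 6.76, Gjb5 6.63, Krt19 6.55, Cldn4 6.497, Krt8 6.49, Gsta1 6.34, Ddah1 6.17, Igf2 5.53, Gsto1 5.52, Fgfr2 5.38, Tead4 5.21, Elf5 5.18, Slc38a4 4.92, Rhox6 4.92, Rhox4a 4.91, Id2 4.89, Klhl22 4.65, Rhox4e 4.35, S100a6 4.21, Asns 4.17, Rhox4c 4.14, Klf5 4.11, Tex19.1 4.05, Ctsz 3.90, Slc2a1 3.72, Fam151a 3.595, AA467197 3.58, Pecam1 3.26, Vti1b 3.16, Rtkn 3.10, Mdm2 2.73, Cited1 2.702, Uqcrc1 2.63, Rcl1 2.57, Psat1 2.55, Ash2l 2.49, Tet2 2.48, Ndufa9 1.56 and Uqcrc2 1.35. It was below 0 for the others: Id3 -5.75, Ifitm2 -3.84, Ifitm3 -3.83, Gstt2 -3.51, Cyct -3.47, Calca -3.40, Otx2 -3.34, Pou5f1 -3.29, Cox6b2 -3.05, Dtx1 -3.001, Dtx3 -2.92, Slc16a3 -2.85, Nnat -2.83, Bcl11a -2.81, Pla2g1b -2.56, Dnmt3a -2.46, Dnmt3b -2.43, Lin28a -2.30, Snhg12 -1.96, Cox6c -1.35 and Cox5b -0.95.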

How the results depend on the processing

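The fit without 3 KO ICM libraries, the fit with detected genes, the fits without 3 other KO ICM libraries, the sex covariate at E5.5 and for the difference, and the added methylation settings were chosen after the data were seen. Of the named genes in the ICM, 2054 of 2325 values kept direction and side of the threshold, 231 lost and 35 gained a call, and 5 reversed. Those 5 reversed with detected genes as a covariate, to 0.11 for Slc2a8, 0.28 for Pgam1, 0.0078 for Aurka, 0.0265 for Shmt2 and 0.60 for Mest. At E5.5 1291 of 1363 kept theirs and 72 lost a call, and for the difference of effects 304 of 304 kept theirs. The latter are values of 10 genes named for the smallest adjusted p of that same test, so their share is raised by that choice. The 1540 ICM genes were 671 after quantile normalization, 882 after median ratio scaling, 405 without the 3 KO libraries with the fewest genes (246 to 2517 without 3 others), 0 with detected genes as a covariate (limma, 314 at an unadjusted p under 0.05), and 946 to 1875 leaving out each library. ICM lists were 5 after quantile normalization, 3 with the replicate block and 1 to 2 leaving out each library. The 2032 genes at E5.5 were 561 with 4 groups in 1 fit and 1205 to 2185 leaving out each library; the 7 lists were 0 with an estimated correlation and 6 to 7 leaving out each library. The 827 genes whose effect differed were 520 with a pseudocount of 0.1, 1664 with array weights and 458 to 1034 leaving out each library. Development gave 2670 to 3435. Lists outside the random range were 5 to 9 in E4.5 epiblast and 3 to 4 in primitive endoderm, and 28 of 238 and 17 of 88 list medians moved. The methylation difference of 5.0 points was 0.29 as a median over sites, 2.45 to 8.27 leaving out each cell, 3.8 and 0.79 at 10 and 20 reads or more, 2.83 over each cell's positions and 2.43 over pooled reads. The cause was not tested for any of these. Replicate numbers did not pair the embryos: correlations across genes of deviations from the group mean, between embryos of the same number, ran from -0.133 to 0.155 in the ICM, with 2 of 7 best with their own number, and from -0.0224 to 0.118 at E5.5, with 2 of 3. As a block they gave 1221, 1950, 578 and 2993 genes. A sex covariate gave 1677 genes and 6 lists at E5.5 and 718 genes for the difference. Not run were alternatives for Rbbp5, not analysed here. Depth is unknown, so what it limits cannot be stated.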

Other observations

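AA467197, which encodes a small mitochondrial protein, rose in KO at both embryo stages, by 1.42 in the ICM (adjusted p = 0.00763; 7 of 7 KO libraries) and at E5.5 (adjusted p = 0.000382; 3 of 3). It was chosen after its values were seen. In the ICM it had 585.8 ± 230.7 FPKM in WT and 1782 ± 1243 in KO (SD, n = 7 each), and at E5.5 1.26 ± 0.498 in WT and 90.7 ± 82.1 in KO (SD, n = 3 each). The E4.5 epiblast cells had 2.59 to 4.85 FPKM in WT and 7.74 to 264.2 in KO, and the primitive endoderm cells 5.99 in WT and 1.57 and 2.68 in KO. The metallothionein genes Mt1 and Mt2, which bind metals, were chosen the same way. In the ICM Mt2 rose from 1181 ± 409 to 3165 ± 1773 FPKM (SD, n = 7 each), and Mt1 rose by 1.08 (adjusted p = 0.00920 and 0.0239; 6 of 7 KO libraries each). At E5.5 Mt2 rose by 1.38 and Mt1 by 1.17 (adjusted p = 0.00223 and 0.00613; 3 of 3 each). Tests by limma; with the number of detected genes as a covariate 0 ICM genes are called (314 at an unadjusted p under 0.05), these 3 included, and other settings were not run for them.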
